A study of Caenorhabditis elegans with 3 samples.

How the data were processed

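Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Caenorhabditis elegans larvae of the L4 stage, with a tag of green fluorescent protein on the product of R02D3.7, the gene now named rcat-1. Per the labels, the strain OP218 carries the insertion wgIs218 in an unc-119 mutant background, and the 3 samples are biological replicates of 1 group. Replicates 1 and 2 carry a fragment size range and a stock centre as source, and replicate 3 carries sonication with a microtip and a laboratory as source. The samples hold no second condition, so no comparison between groups was made, and the control alignment named in the deposited descriptions was not analysed here.

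Per the deposited description files, peaks were called on each replicate's alignment against 1 control alignment, and once more on the 3 alignments together, which gives the pooled list. The authors then derived a thresholded list from the pooled and the 3 replicate lists by the irreproducible discovery rate. The aligner, the peak caller and its settings, and the cutoff of the irreproducible discovery rate are not given in the sources used here. The deposited signal of a peak is the strength the authors' caller gave it, and it was used to rank and describe peaks within a list. The deposited −log10 q of each peak takes the same value in all 390 thresholded peaks, so it was not used for ranking. Read counts are not part of these lists, so the depth of each replicate is unknown and a peak's signal has no counting error here. The calling of the pooled list from the same reads as the replicate lists raises their overlap, and a control shared between replicates can add the same false peaks to each.

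Both a ce10 and a ce11 version of the 5 lists were read. The main results use ce11, which has the sequence of the WBcel235 reference, and no peak ended beyond a chromosome of that reference. Coordinates are 1-based. Genes and transcript starts came from Ensembl release 115. The 15363 piRNA genes were left out of the transcript starts, a choice made with the files at hand and before any result was computed, which left 31563 genes. The ce10 lists were used only where no annotation is needed, with the ce11 chromosome lengths as expectation for peaks per chromosome.

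A thresholded peak counted as supported by a replicate when one of the 1950 strongest peaks of that replicate, 5 times the number of thresholded peaks, had its summit inside it. Chance support came from 9999 random placements of the peaks on their own chromosomes. Pairs of replicates were compared by the share of their 1000 strongest peaks that overlapped by at least 1 bp. A promoter peak had its summit from 1000 bp upstream to 200 bp downstream of a transcript start, and the share was tested against 9999 random placements, one-sided. Peaks outside promoters were put, in this order, in 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence. Peaks per chromosome were tested against length by chi-square with 99999 Monte Carlo draws and by exact binomial tests. Shares carry exact 95% Clopper-Pearson intervals, which treat peaks or genes as independent.

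Genes with a promoter peak were counted in 40 lists, 31 of protein-coding genes chosen by symbol and 9 of RNA genes and pseudogenes by biotype, with Fisher's exact test, two-sided. The background was the other protein-coding genes or, for the biotypes, all other genes except piRNA genes. The annotation holds long non-coding RNA genes under the biotype lincRNA, which was used for that list. All 2080 6-mers, counted on both strands, were compared between the 101 bp round each summit and an equal window centred 300 bp to a randomly drawn side, by an exact sign test, two-sided. Peaks within 20 kb of rcat-1 and unc-119 were compared with the same window round 9999 random nuclear genes, one-sided. All adjusted p-values are Benjamini-Hochberg values within a family of tests.

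The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. Named are rcat-1 and unc-119, the genes whose promoter windows hold the 25 strongest thresholded peaks (the nearest start where there are several, and the nearest start at any distance where there is none), the 4 members with the strongest peaks of each list past an adjusted p of 0.05, and the 2 genes with the strongest peaks of each RNA biotype. Other genes named as sharing a peak were chosen after their values were seen.

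The procedures were tested on simulated data. With 364 random positions, 2 of 100 runs of the promoter test gave a p under 0.05, and none of the 6-mers passed in 5 runs. A 6-mer planted in 61 of 364 peaks came out at rank 1. With random genes, 2% of 50 runs had any list past the threshold, and 1 planted list of 100 genes was recovered alone. These genes were drawn singly, whereas a real peak can mark several neighbouring genes, so the error rate with such clusters is not covered. With no effect of chromosome, 5.5% of 200 runs had any chromosome past the threshold. Of 215 peaks with planted support, 214 were recovered, and 6 peaks without planted support were counted as well. The simulated replicates were subsets of the thresholded peaks at unchanged positions, with no other peaks. This run therefore checks the counting and not the rate of false support in real lists. Alternatives changed 1 choice at a time: the overlap rule, the number of replicate peaks, the promoter window, the background, the control sequence, the 195 strongest thresholded peaks, the ce10 files and leaving out each replicate in turn. For the last, the thresholded peaks supported by both other replicates were kept, and pairs were reduced to the remaining pair. No list was called anew, so the reads of a replicate left out still shaped the peaks. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.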

Results

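The binding of the tagged product of rcat-1 (R02D3.7, WBGene00019824), a protein with a C2H2-type domain, was mapped in L4 larvae of both sexes in 3 biological replicates. The authors' thresholded list held 390 peaks in ce11, of which 364 were nuclear and 26 lay on the mitochondrial genome, and overlapping peaks merged into 366 separate regions. These were the 390 strongest of the 11533 peaks in the pooled list. The replicate lists held 27624, 28357 and 30000 peaks in replicates 1, 2 and 3. The median width of a thresholded peak was 430 bp and its signal, as the authors' caller gave it, ranged from 35.6 to 901 with a median of 60.9. Signals were not compared between lists.

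The strongest peak lay at the promoter of rcat-1 itself, on chromosome IV from 255281 to 256056, with a summit 212 bp upstream of the gene's start and a signal of 901. The second, on chromosome IV from 4749728 to 4750377 with a signal of 808, lay between Y17G9B.5 and rpl-20, which encodes a protein of the large ribosomal subunit. The third, on chromosome II from 10387952 to 10388547 with a signal of 794, was intergenic and lay in no promoter window, the nearest start at any distance being that of the ncRNA gene T09F3.6 at 1746 bp. Next came the promoters of rbc-2, whose window is shared with the respiratory complex I gene ndua-8 (signal 594), F25B4.4, shared with hmgs-1 of the mevalonate pathway (519), sco-1, a gene for an assembly factor of cytochrome c oxidase (515), R02D3.8 (492) and gtsf-1 of the small RNA pathways (457).

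Of the 25 strongest peaks, 24 had their summit in a promoter window and 24 were supported by all 3 replicates. The nearest starts at the others were those of ska-3, in a window shared with rps-12 (signal 423), R05D3.8 (408), rpl-15 (388), rpl-23 (383), dvc-1 (370), frg-1, in a window shared with the ubiquitin gene ubq-2 (358), exos-2 (336), F54D10.5 (315), pph-5 (304), nbet-1 (304), rbm-5 (299), rps-24 (296) and mrps-7 (273). LLC1.120 and F09E5.18, both ncRNA genes, had the nearest starts at peaks with signals of 304 and 285, and the window of the former peak was shared with dld-1, which encodes dihydrolipoamide dehydrogenase. Both mitochondrial peaks among the 25 fell in the window of the tRNA gene MTCE.36, with signals of 387 and 272.

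Whether the replicates found the same sites was asked first of the thresholded peaks. All 3 replicates supported 280 of the 390 peaks (71.8%, exact interval 67.0% to 76.2%), against a mean of 10.7 in random placements (p = 0.0001, the smallest they can give). Exactly 2 replicates supported 103 peaks, 1 replicate supported 7, and no peak was without support. Replicates 1, 2 and 3 supported 371, 335 and 347 peaks. Among nuclear peaks 264 of 364 had full support, and among mitochondrial peaks 16 of 26. The random mean was not split between these sets. Chance support can be higher on the mitochondrial genome, of which thresholded peaks cover 58.4%, so the 16 of 26 has no chance level of its own. The thresholded list was made from the same reads, so the support from the replicates is not independent of it. With as many replicate peaks as thresholded peaks, 184 peaks had support from all 3 replicates.

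Of the 1000 strongest peaks of each replicate, 44.15% were shared between replicates 1 and 2, 45.3% between 1 and 3, and 41.55% between 2 and 3, a mean of 43.7% ± 1.92 (SD, n = 3 pairs). Signals of shared peaks had Spearman correlations of 0.64, 0.70 and 0.70, which are across peaks within these libraries, and peaks are not independent replicates. Replicate 3, whose labels differ in fragmentation and source, shared as large a part with replicate 1 as replicate 2 did, within this spread; 3 pairs allow no test. The shared part fell to 33.8% with 2000 peaks and rose to 57.8% with 500.

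Where the sites lie relative to genes was described by class. Promoter windows held 320 of the 364 nuclear peaks (87.9%, exact interval 84.1% to 91.1%), against 34.2% at random positions on the same chromosomes (p = 0.0001, one-sided, the smallest the placements can give). Introns held 14 nuclear peaks (3.85%, where 26.4% of the sequence is intronic), intergenic sequence 21, 5' UTRs 3, 3' UTRs 3, coding exons 2 and other exons 1. Over the 271 nuclear peaks in the window of a protein-coding start, the median summit lay at -171 bp from the nearest such start, with quartiles of -277.5 and -74.5 bp, and 243 of the 271 summits were upstream. The window spans 1000 bp upstream and 200 bp downstream, so most random positions in it would lie upstream too, and the 243 were not tested against them. With the mitochondrial peaks included the share was 88.5% (345 of 390), but promoter windows cover 91.2% of the mitochondrial genome, so the class says little there.

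Chromosome X held 36 nuclear peaks where its length would give 64.3 (0.56 times, exact binomial test, adjusted p = 0.000273), and chromosome V held 53 against 75.96 (adjusted p = 0.0048). Chromosome III held 75 against 50.04 (exact test, adjusted p = 0.000968). Chromosomes I, II and IV, with 69, 66 and 65 peaks against 54.7, 55.5 and 63.5, did not pass. Over the 6 nuclear chromosomes the Monte Carlo p was 1e-05, the smallest the draws can give. The mitochondrial genome of 13794 bp held 26 peaks against 0.054 expected from length, an expectation that takes no account of its copy number. With the mitochondrial genome counted as a seventh chromosome, X held 0.522 times its expectation over all 390 peaks and 0.319 times in the 195 strongest (11 against 34.5, exact test, adjusted p = 4.07e-06). In the 195 strongest, chromosome V was about as far below expectation (28 against 40.7, 0.688 times, and 0.651 over all peaks) but did not pass the exact test (adjusted p = 0.0633). Chromosome III, with 33 against 26.8 (1.23 times) where all peaks gave 75 against 53.6, did not pass the exact test either (adjusted p = 0.323).

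**Figure D1:**
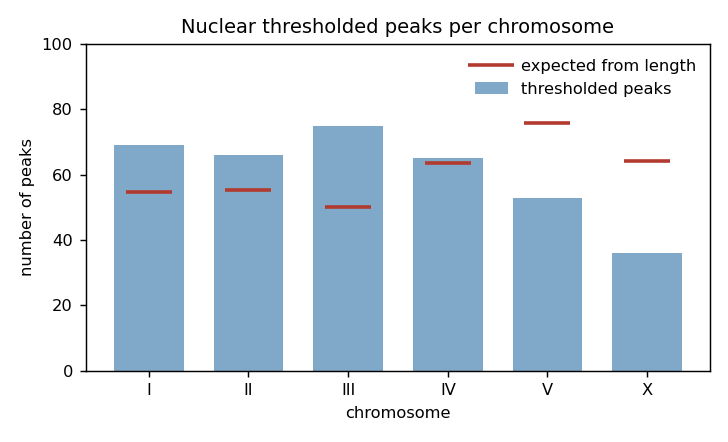
Bars give the number of nuclear thresholded peaks on each chromosome (vertical axis) and red lines the number expected from chromosome length. Chromosome X holds 36 peaks against 64.3 expected and chromosome III 75 against 50.04.

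Genes for the protein synthesis machinery and for respiration had promoter peaks more often than other protein-coding genes. Of 79 cytosolic ribosomal protein genes, 25 had one (31.6%, exact interval 21.6% to 43.1%), 16.4 times the 1.93% of the other protein-coding genes (Fisher's exact test, adjusted p = 1.04e-21), led by rpl-20, rps-12, rpl-15 and rpl-23. Of 51 listed genes for the respiratory chain and ATP synthase, 11 had one (21.6%, 10.8 times, exact test, adjusted p = 3.51e-08), led by the cytochrome c oxidase subunit gene cox-5B (signal 222), sdhb-1 of complex II (121), cox-10 (112), whose product makes haem for the oxidase and is no subunit of it, and nuo-6 of complex I (109). The list was chosen by symbol and does not hold ndua-8, the complex I gene in the window of the stronger rbc-2 peak. Its count and order therefore cover the listed genes alone. Translation factors had 6 of 39 (15.4%, 7.61 times, exact test, adjusted p = 0.000652), led by eif-2gamma (128), the eIF4G gene ifg-1 (121), eif-2beta (77.4) and eif-2Bgamma (65.6). Mitochondrial ribosomal protein genes had 7 of 70 (10%, 4.95 times, exact test, adjusted p = 0.00251), led by mrps-7 (273), mrpl-40 (167), mrps-6 (139) and mrpl-49 (136).

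Germline genes had promoter peaks at 6 of 65 (9.23%, 4.56 times, exact test, adjusted p = 0.00846), led by the Nanos family gene nos-3 (202), the Argonaute gene wago-4 (85.8), him-19 (66.6), which acts in meiosis, and puf-9 (63.5), a Pumilio family gene that also acts in the larval epidermis. Among genes with any pooled peak at the promoter, 4 of the 40 lists passed the exact test: ribosomal proteins (3.95 times, adjusted p = 5.82e-08), the respiratory chain (3.59 times, 0.00136), snoRNA genes and ncRNA genes. In that background the ratio was 2.01 for mitochondrial ribosomal proteins (exact test, adjusted p = 0.267), 3.05 for translation factors (0.0630) and 2.56 for germline genes (0.130), and with only the nearest start counted it was 2.51 for mitochondrial ribosomal proteins (0.403) and 2.70 for germline genes (0.399). With genes whose upstream neighbour lay over 500 bp away as background, the ratios were higher: 30.5 for ribosomal proteins, 36.4 for the respiratory chain, 11.9 for mitochondrial ribosomal proteins (3 of 21), 8.60 for germline genes (3 of 29) and 11.8 for translation factors (2 of 14, exact test, adjusted p = 0.0547).

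Several large gene families had few peaks. Chemoreceptor-type receptors had 1 of 1364 (0.0733% against 2.19%, exact test, adjusted p = 1.70e-10), sre-23. F-box, MATH and BTB genes had 1 of 412 (adjusted p = 0.0145), fbxc-54, and nuclear hormone receptors had 0 of 274 (exact upper bound 1.34%, adjusted p = 0.0259). Among genes with any pooled peak the counts were 1 of 82 (0.127 times other genes, exact test, adjusted p = 0.0502), 1 of 28 (0.375 times, 0.829) and 0 of 33 (0.256). For nuclear receptors, still with no gene, the adjusted p was 0.0577 without replicate 3 and 0.0506 to 0.431 under 4 other settings. For F-box, MATH and BTB genes, at 0.116 times other genes in the full comparison, the ratios stayed low where the test was no longer passed, at 0.142 with a narrower window (exact test, adjusted p = 0.0506), 0.208 with only the nearest start (0.323) and 0 with a distant upstream neighbour (0.338). The lists of vacuolar ATPase, moulting, heterochronic, muscle, neuronal, intestinal and sperm genes had no promoter peak, which did not set them apart from other genes by the test. Aminoacyl-tRNA synthetases (3 of 32), proteasome subunits (3 of 33), heat shock proteins (4 of 59) and cell cycle genes (4 of 66) did not pass either, with adjusted p of 0.0837, 0.0843, 0.0869 and 0.109. Nor did splicing factors (2 of 46), histones (1 of 81), collagens (2 of 174), neuropeptides (1 of 143), epidermal genes (1 of 78), homeobox genes (1 of 97), other transcription factors (3 of 199), C-type lectins (1 of 240), xenobiotic enzymes (1 of 202), Wnt, TGF-beta, Notch and EGF genes (1 of 51), lipid metabolism (1 of 118) and ion channels (1 of 234).

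**Figure D2:**
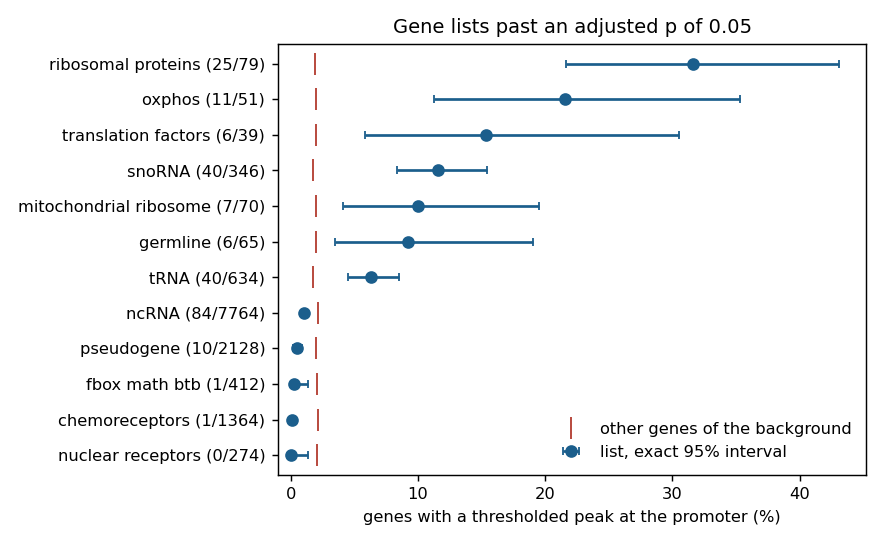
Points give the percent of each list's genes with a thresholded peak at the promoter (horizontal axis) with the exact 95% interval, and red marks the percent among the other genes of the background, for the 12 lists past an adjusted p of 0.05. Ribosomal proteins reach 31.6% and nuclear receptors 0%; oxphos stands for the respiratory chain and ATP synthase.

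Genes for small structural RNAs also carried peaks. Of 346 snoRNA genes, whose products guide the modification of other RNAs, 40 had one (11.6%, 6.49 times other genes, exact test, adjusted p = 1.24e-18), led by F54E7.11 and F54E7.10 in a peak shared with rps-12 and ska-3, and by K11H12.13 and K11H12.12 in the peak of rpl-15. Counting only RNA genes that share no peak with a protein-coding gene, an alternative chosen after the data were seen, there were 20 snoRNA genes (5.78%, 3.90 times, exact test, adjusted p = 3.24e-06). The snoRNA ratio was 3.08 in the 195 strongest peaks (11 genes, exact test, adjusted p = 0.00543) and 2.82 among genes with any pooled peak (adjusted p = 5.82e-08). Of 634 tRNA genes, 40 had a peak (6.31%, 3.51 times, exact test, adjusted p = 3.94e-10), but 20 of the 40 are mitochondrial, among them MTCE.36, MTCE.22 (signal 219), MTCE.24 (212) and MTCE.32 (201). Among nuclear genes the ratio for tRNA genes was 1.86 (exact test, adjusted p = 0.0408), without shared peaks it was 2.22 (adjusted p = 0.00643), and among genes with any pooled peak it was 1.19 (adjusted p = 0.710). With genes whose upstream neighbour lay over 500 bp away as background, 4 of 84 tRNA genes had a peak (4.42 times, exact test, adjusted p = 0.0547).

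The ncRNA genes (84 of 7764, 0.50 times, exact test, adjusted p = 1.96e-09) and pseudogenes (10 of 2128, 0.24 times, adjusted p = 6.83e-08) had fewer peaks than other genes. The strongest were at LLC1.120, F09E5.18, B0393.12 (223) and F26E4.16 (222) for ncRNA genes, and at T07A9.1 (296), VW02B12L.t1 (94.2), B0547.5 (92.1) and C06A1.4 (67.2) for pseudogenes, T07A9.1 sharing its peak with rps-24. Counting only those that share no peak with a protein-coding gene, the ratios were 0.174 for ncRNA genes (26 of 7764) and 0.0865 for pseudogenes (3 of 2128). In the 195 strongest peaks the ratio of ncRNA genes was 0.281 (28 genes), and among genes with any pooled peak that of pseudogenes was 0.913 (10 of 121, exact test, adjusted p = 1). Of 129 snRNA genes 6 had a peak (exact test, adjusted p = 0.0901), led by the trans-splicing leader genes sls-2.1 (80.6) and sls-2.4 (67.4). The mitochondrial rRNA genes MTCE.33 (201) and MTCE.7 (200) were the 2 of 22 rRNA genes with a peak. For miRNA genes 4 of 261 had one, led by cel-mir-2213 (79.2) and cel-mir-354 (49.2), for antisense RNA genes 1 of 100, anr-58 (133), and for lincRNA genes 0 of 194, and neither these 3 biotypes nor rRNA genes passed the test.

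The sequence under the summits was described by its 6-mers. CGTAAA, or TTTACG on the other strand, lay within 50 bp of 177 of the 390 summits (45.4%) and in 18 flanks (4.62%, exact sign test, adjusted p = 1.69e-36). The next were ATTTAC (45.4% against 9.23%) and GATTTA (42.6% against 10.8%), which overlap it, and CGACAC (24.6% against 3.33%). ACACTC (17.4% against 1.79%) and ACGCGC (15.1% against 1.79%) share less with it. In all, 165 of 2080 6-mers passed, 116 of them more frequent at summits and 49 less frequent, the latter led by CTGAAA (8.21% against 23.6%). The counts for neighbouring 6-mers are not independent, since they overlap.

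The strain carries an inserted copy of the tagged gene, and peaks in the surroundings of that gene were counted. Within 20 kb of rcat-1, which lies on the minus strand of chromosome IV from 253619 to 255429, there were 6 thresholded peaks against a median of 0 round random genes (p = 0.0003, one-sided permutation over random genes) and 18 pooled peaks against a median of 4 (p = 0.0052). The thresholded peaks lay at the promoters of rcat-1 (signals 901 and 68.7, with 1 interval listed with 2 summits), R02D3.8 (492), cogc-8 (201), dpy-9 (43.3) and aass-1 (37.04). Round unc-119, whose mutation the strain carries, there was no thresholded peak and 1 pooled peak (p = 0.936 in the same permutation).

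**Figure D3:**
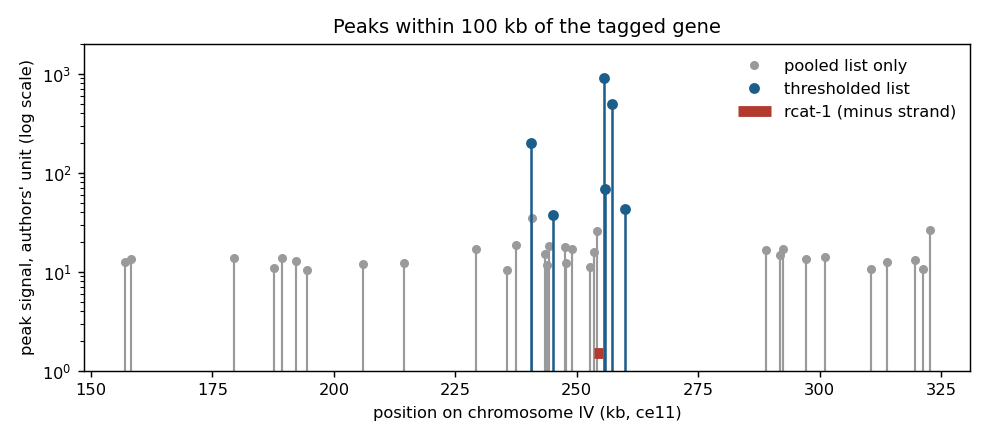
Each stem is a peak within 100 kb of rcat-1, with its summit position on chromosome IV (kb, ce11) on the horizontal axis and the authors' peak signal on a log vertical axis; blue stems are in the thresholded list, grey stems in the pooled list alone, and the red bar is the gene. The 6 thresholded peaks lie within 20 kb of the gene, the strongest with a signal of 901.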

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

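The 8-mer CGTAAATC was chosen after the 6-mers at the summits had been seen, the tests of mitochondrial coverage and of ribosomal protein genes by the sequence in their windows and by peaks of like rank were also chosen after the results had been seen, and the count round the tagged gene was planned but its reading as transgene copies was not. Pooled peaks below the authors' threshold enter no sequence comparison of the report, and they held a signal of their own: CGTAAATC lay within 50 bp of the summit in 2.23% of the 11143 nuclear ones (249 peaks, exact interval 1.97% to 2.53%) and in 1.26% of their flanks (exact sign test, p = 2.96e-09). A count of 0 would allow 3 of the 11143, or 0.0269%. By rank the share was 8.20% in peaks 391 to 1000 (50 of 610, flanks 1.64%), 4.60% in peaks 1001 to 2000 and 2.33% in peaks 2001 to 5000. From peak 5001 on it was 1.27% against 1.15% in flanks, a difference that did not pass (exact sign test, p = 0.549).

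The 26 mitochondrial peaks were also the full set of mitochondrial peaks in the pooled list. The values argue against the leading 6-mer of nuclear summits as their source: CGTAAA lay at 7.69% of mitochondrial summits (2 of 26, with 3 in flanks) and at 48.1% of nuclear ones (175 of 364, Fisher's exact test, p = 2.50e-05). They do not bear on shared sequence in general, since 189 nuclear peaks lack CGTAAA too. Other sequences were not examined under the mitochondrial peaks. Signal along the whole molecule from abundant mitochondrial DNA may also give such peaks, and there the result stays open, because pooled peaks covered 58.4% of the mitochondrial genome, between the bounds of 50% and 70% set for the test. No other biological explanation was tested.

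The strongest peak of the list lay at the tagged gene, and extra copies of the locus in the inserted transgene could raise the signal of its neighbourhood. The count of 18 pooled peaks within 20 kb (p = 0.0052, permutation over random genes) goes with that explanation. It is a number of peaks, though, which includes the 6 thresholded ones, and raised signal itself was not tested. All 18 lie in the 30 kb from -20 to 10 kb of the gene's left end, which is also where the 6 thresholded peaks lie. A direct binding of the protein to its own promoter stays open, since the strongest rcat-1 peak and those of R02D3.8 and cogc-8 hold CGTAAATC and the other 3 do not. A transgene-free sample would be needed to separate these, and none was analysed here.

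Ribosomal protein genes were over-represented, and any accessible promoter might give signal in this assay. Among genes with any pooled peak at the promoter they stayed over-represented (25 of 70 against 9.04% of the others, exact test, adjusted p = 5.82e-08), which argues against the presence of a peak as the whole cause but not against a relation between accessibility and peak strength, which was not measured. Over all ribosomal protein genes, with or without a peak, CGTAAA lay in the promoter windows of 63.3% (50 of 79, exact interval 51.7% to 73.9%), against 43.9% of other protein-coding genes (exact test, p = 0.000597), so the sequence is a candidate explanation for part of the excess. By presence alone CGTAAA is not the whole of it. Ribosomal protein genes were over-represented 10.4 times among genes with CGTAAA in the window (19 of 50 bound, exact test, p = 7.77e-15). Among genes without it they were over-represented 35.03 times (6 of 29, exact test, p = 2.41e-08). The longer CGTAAATC lay in 16 of 79 ribosomal protein windows (20.3%), against 6.85% of others (exact test, p = 8.33e-05). With CGTAAATC, 14 of 16 ribosomal protein genes were bound, against 17.2% of other genes (5.08 times, exact test, p = 2.41e-09). Without it, 11 of 63 were bound, against 0.804% (21.7 times, exact test, p = 5.64e-12). The presence of CGTAAATC is thus not the whole of the excess either. At the summits of ribosomal protein peaks CGTAAA lay in 38.5% (10 of 26, exact interval 20.2% to 59.4%) and in 49.7% of other nuclear promoter peaks, a difference that was not detectable in the test set beforehand (exact test, p = 0.311), while promoter peaks of like rank would give 16.01 of the 26 (one-sided permutation within bins of 40 ranks, p = 0.00268), a comparison among peaks alone that does not bear on how often a promoter is bound.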

How the results depend on the processing

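Alternatives on chromosomes, transcript starts, shared RNA peaks, peaks near the tagged gene, the other flank and distances of 10 and 50 kb were added after the data were seen. Full replicate support (280 peaks) fell to 184 with as many replicate peaks as thresholded peaks, by construction. It was 297 to 330 with 1 replicate left out, where only the 2 others had to support a peak, so that rise is by construction too. Pairwise sharing (43.7%) was 57.8% with 500 peaks, 33.8% with 2000, 63.6% with as many as thresholded, 34.8% with reciprocal overlap of 50% and 31.9% with summits within 100 bp, and 41.55% to 45.3% with 1 replicate left out. The fall with reciprocal overlap is by construction, as that rule is stricter, and leaving out a replicate only returns a single pair. The cause of the other changes was not tested. The promoter share stayed past its test in all 11 alternatives (range 75.9% to 96.4%). Chromosomes past the test went from 4 to 2 in the 195 strongest peaks, and the cause was not tested. Lists past the test went from 12 to 4 with genes with any pooled peak as background, which has fewer genes but in which ratios also moved towards 1 (tRNA genes from 3.51 to 1.19, pseudogenes from 0.236 to 0.913). They were 8 with only the nearest start and with a distant upstream neighbour, 10 with the narrower promoter window, and 11 to 14 with 1 replicate left out. The 6-mers higher at summits went from 116 to 73 with 25 bp on each side, a shorter sequence, were 107 to 125 with 1 replicate left out and 132 with the other flank, and CGTAAA led in all 10 alternatives. Of 183 values for single lists, chromosomes, the leading 6-mer and pooled peaks near the tagged gene, 161 kept their direction and side of the threshold, 22 kept the direction but no longer passed, and none reversed. Some of the 161 could hardly change. The setting on shared RNA peaks leaves the counts of protein-coding lists as they were, and leaving out a replicate keeps a subset of the same peaks. The unknown read depth limits what absent peaks can show.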

Other observations

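The tests in this part were chosen after the leading sequence had been seen, and for the X chromosome the bounds were set before its sites were counted. The peaks of snoRNA and nuclear tRNA genes held the leading 6-mer less often than other nuclear promoter peaks. CGTAAA lay at 3 of 37 nuclear peaks with a snoRNA gene in the window (8.11%, exact interval 1.70% to 21.9%), against 54.1% of the other nuclear promoter peaks (Fisher's exact test, adjusted p = 2.31e-07 over 7 lists). It lay at 0 of 19 peaks with a nuclear tRNA gene in the window (exact upper bound 17.6%), against 51.8% (adjusted p = 8.49e-06). These peaks were weaker, with median ranks of 246 and 313 against 181 and 183 for the others, and weaker peaks hold the sequence less often. Peaks of like rank, in bins of 40 ranks, would give 14.1 of the 37 and 4.03 of the 19 (one-sided permutation within bins, p = 1e-05, the smallest the draws can give, and p = 0.00417). Peaks of germline genes (5 of 6), respiratory chain genes (7 of 11), translation factors (3 of 6) and mitochondrial ribosomal proteins (2 of 7) did not differ from the others by Fisher's exact test, which takes no account of rank.

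The share of nuclear peaks with CGTAAATC fell with rank, from 73.8% in the 100 strongest thresholded peaks (62 of 84) over 47.3% in peaks 101 to 200 and 32.3% in peaks 201 to 300 to 13.3% in peaks 301 to 390 (12 of 90, flanks 4.44%, exact sign test, p = 0.0215). Within 100 bp of the summits, 175 nuclear peaks held 205 sites, at a median of 26 bp from the summit. Counted from 1 at the first base of the 8-mer, position 9 was G in 49.3% and T in 27.3% of sites, and positions 10 to 13 were most often A (86.8%), C (85.9%), A (82.9%) and C (62.4%). The longer CGTAAATCGACAC is itself frequent in the nuclear genome, with 1638 occurrences, 26.03% of the 6292 occurrences of the 8-mer, and it lay in 32.2% of the peaks that hold the 8-mer. The 51 bp round the site occurred once in the nuclear genome for 148 of 149 peaks.

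The 189 nuclear peaks without CGTAAA lay at promoters about as often as those with it (86.8% and 89.1%). These windows include those of RNA genes, and CGTAAA lay at 3 of 37 snoRNA peaks and 0 of 19 nuclear tRNA peaks. Like shares thus do not mean like genes, and the share at protein-coding promoters was not compared. In the peaks without CGTAAA, 4 6-mers passed the exact sign test. ACACAC (16.9% against 3.17% of flanks, exact adjusted p = 0.016), ACACTC and CGCCGC were more frequent at summits, and AATTTG was less frequent (6.35% against 21.7%).

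A hypothesis for the low number of peaks on chromosome X is that the sequence is rarer there. Against protein-coding starts in place of length, X held 0.663 times its expectation and V 0.574 times, so X was not the lowest. CGTAAATC occurred 21.2 times per Mb of protein-coding promoter windows on X and 67.8 times on the autosomes, a ratio of 0.313 (exact interval 0.247 to 0.391), below the bound of 0.7 set for it. Over the autosomes, too few for a correlation, the sites per Mb and the peaks were 50.1 and 66 for II (length gives 55.5), 54.1 and 53 for V (75.96), 68.1 and 65 for IV (63.5), 82.2 and 75 for III (50.04), and 97.99 and 69 for I (54.7). On X the shortfall was seen in peaks with the sequence, 5 of 149 on X where length gives 26.3 (exact binomial test, p = 1.34e-07), and was not detectable in peaks without it, 31 of 215 where length gives 37.99 (p = 0.245). Several of the 31 had a tRNA gene in the window, a class of nuclear peaks without CGTAAA (0 of 19). This comparison and that of tRNA genes thus share peaks, and X without its tRNA peaks was not tested. A shortfall on X among the other peaks without the sequence therefore stays possible, and the split does not tie the shortfall to the sequence alone. Peaks with the sequence are also the stronger ones, and those on X were weaker, with a median rank of 269 against 200.5 for other nuclear peaks. Nuclear peaks of like rank, in bins of 40 ranks, would give 10.6 with the sequence among the 36 on X, against the 5 seen (one-sided permutation within bins, p = 0.0154). The sequence was found in these same peaks, so its rarity on X may account for the shortfall only as a hypothesis, and lower expression of genes on X in the germ line was not tested.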
